A study of Drosophila melanogaster with 5 samples.

How the data were processed

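Messenger RNA levels were measured in Drosophila melanogaster S2 cells, an embryonic line with macrophage-like features, on 5 Affymetrix expression arrays. Per the labels' protocols, cells were treated with 10 µg of double-stranded RNA for 1 hour in serum-free medium and then kept in serum-containing medium for 6 days at 26°C. The double-stranded RNA targeted NSL1 on 2 arrays and glutathione S-transferase, the control, on 3 arrays. Which glutathione S-transferase the control RNA matched is not given in the sources used here. Total RNA was extracted with Trizol, purified on columns and labelled with biotin, per the labels' protocols. Groups and replicate numbers came from the sample titles. Nothing in the labels states that replicates were separate cultures, so p-values measure only the spread between these arrays.

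The deposited values were log2 expression values, 1 per probe set and array, made by the authors with GCRMA, per the submitters' processing notes. GCRMA corrects background for probe sequence, normalizes between arrays and summarises the probes of a set. The version and whether all 5 arrays were normalized together are not given in the sources used here. The log2 scale was inferred from the values, which ran from a floor of 2.21 to 15.8. Of 18952 probe sets, 183 were control probe sets of the manufacturer. On all 5 arrays, 9179 probe sets lay within 0.01 of the floor. GCRMA pulls dim signals towards this floor, so that small differences between absent transcripts are removed and the spread of dim probe sets is understated. Between-array normalization removes a change common to all transcripts.

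Probe sets were named from the platform annotation. A single gene symbol was given for 13647 probe sets, several for 402 and none for 4903. The gene identifiers of 13544 single-symbol probe sets were found in a gene table of Release 6 of the genome, which updated 1 symbol, and 103 were not found. Probe sets with several symbols or none were tested but not named. Chromosome arms and gene order came from the same table. No coordinates are given, since the build behind the annotation is not given in the sources used here.

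NSL1 RNAi was compared with control RNAi using limma 3.58.1 in R 4.3.3 (lmFit and eBayes, constant variance prior, two-sided, no covariates). Probe sets with a mean of at least 4 over the 5 arrays were tested, and the control probe sets were left out, which left 7225. Calls were made at a Benjamini-Hochberg adjusted p of 0.05. A gene was represented by its tested probe set with the highest mean over the 5 arrays, which gave 5946 genes, of which 278 had more than 1 tested probe set and 8 had probe sets called in opposite directions. Where every array of a group lay under 4, the fold was given as a bound ("at least"), with the mean of that group set to 4. The prior had 1.90 degrees of freedom and each probe set 3 residual ones. The number of arrays limits the precision, and the median standard error of a log2 fold change was 0.14.

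Gene lists were tested with limma's camera at a preset correlation of 0.01, which compares a list with all other genes. Of 30 lists, 28 had the minimum of 5 tested genes, and p-values were adjusted over these. Camera with an estimated correlation and fry, which tests a list by itself, were alternatives. Since 41.4% of all tested genes fell and 23.8% rose, a list can pass fry without differing from other genes, and 18 lists passed it. Without a filter, camera compares a list with many genes at the floor that cannot show a change. X-linked genes were compared with autosomal genes in the same way. Log2 fold changes were also summarised in 4 quartiles of mean expression, without a test. The lists, tests, filter and most alternatives were set before the data were examined. Named genes followed a rule set at the same time. It took every tested member of the NSL and MSL lists, and the 12 largest rises and 12 largest falls among called genes with non-overlapping groups and a symbol other than a bare CG or CR number. It also took up to 4 called members of each list by size of change, or up to 2 uncalled members where none was called. Genes named outside this rule are marked as such.

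The fit was tested on simulated data, with 200 of 7225 probe sets changed in each of 10 runs. It recovered 17% of planted log2 changes of 0.5, 58.4% of changes of 1, 90.4% of changes of 2 and 97.8% of changes of 4. Of its calls, 3.66% were false. The simulated noise was independent between probe sets, and far fewer probe sets changed than the 4607 called in the data. These rates therefore do not carry over to the data. Alternatives covered the filter (none, 3 or 6), median centring, quantile normalization, cyclic loess, the variance prior, least squares without moderation, the replicate number as a block, the mean of a gene's probe sets, the threshold, the set test and leaving out each array. Raising values below 4 to 4 and scaling to the poly-A control probe sets were added after seeing the data. Python 3.11.15 with pandas 2.3.3 prepared the tables, and matplotlib 3.10.9 drew the figures. Scanner files were not used here.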

Results

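The series asked which genes depend on the NSL complex, which contains the histone acetyltransferase MOF and is named in the series title with housekeeping genes. NSL1, a subunit of this complex, was targeted by RNA interference in S2 cells, and transcript levels were compared with those of cells given control double-stranded RNA. There were 3 control arrays and 2 arrays labelled NSL1 RNAi. Values are GCRMA log2 levels, and differences are NSL1 RNAi minus control. Between 37.6% and 38.3% of probe sets lay at or above 4 on each array.

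The transcript of the targeted gene, nsl1, was not measurably reduced. Its level was 11.24 ± 0.05 (SD, n = 3) on the control arrays and 11.10 ± 0.06 (SD, n = 2) on the NSL1-labelled arrays. The log2 difference was -0.14 (SE 0.09, limma adjusted p = 0.199), or 90.5% of the control level with a 95% interval of 77.7% to 105.55%. The probe set therefore did not check the labels, and whether it lies in the part of the transcript that the double-stranded RNA matched is not given in the sources used here. The arrays are called NSL1-labelled for this reason, and every direction below rests on the labels. After renewed quantile normalization the NSL1 transcript difference was -0.28 (limma adjusted p = 0.0463). At the other end of the 16 alternatives run for it, the difference was -0.02.

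Among the other NSL complex genes, Rcd1 rose by 0.45 (SE 0.12, limma adjusted p = 0.0279). Differences were 0.58 for Rcd5, 0.30 for wds, 0.09 for mof and 0.00 for dgt1, none of which passed the test. Of the 6 tested NSL genes, 1 was called over all genes tested and 0 adjusted over the list alone, and the list did not stand apart in limma's camera (adjusted p = 0.301). In the MSL complex, which carries MOF to the male X chromosome, msl-2 fell (-0.74, SE 0.15, limma adjusted p = 0.0101) and msl-3 fell (-0.70, SE 0.14, limma adjusted p = 0.00861). For msl-1 the difference was 0.16 and for mle 0.01, neither past the test. The MSL list had 2 called genes of 5, also adjusted over the list alone, and did not stand apart in limma's camera (adjusted p = 0.968, direction down), with a median of 0.01 and a mean of -0.24. MBD-R2, roX1 and roX2 had no tested probe set of their own. Without NSL1-labelled replicate 1 or 2, Rcd1, msl-2 and msl-3 lost the limma call (adjusted p up to 0.139, 0.0774 and 0.069), and Rcd1 also lost it without control replicate 2. Without control replicate 3, Rcd5 (0.31, limma adjusted p = 0.0101) and wds (0.42, limma adjusted p = 0.0122) passed. The normalization changed calls as well. Under cyclic loess msl-1 (0.61, limma adjusted p = 0.00545) and wds (gene: wds, 0.49, 0.0284) passed and msl-2 did not (gene: msl-2, -0.44, 0.0646), and after quantile normalization msl-1 passed (gene: msl-1, 0.45, 0.0227) and Rcd1 did not (gene: Rcd1, 0.39, 0.0672).

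**Figure D1:**
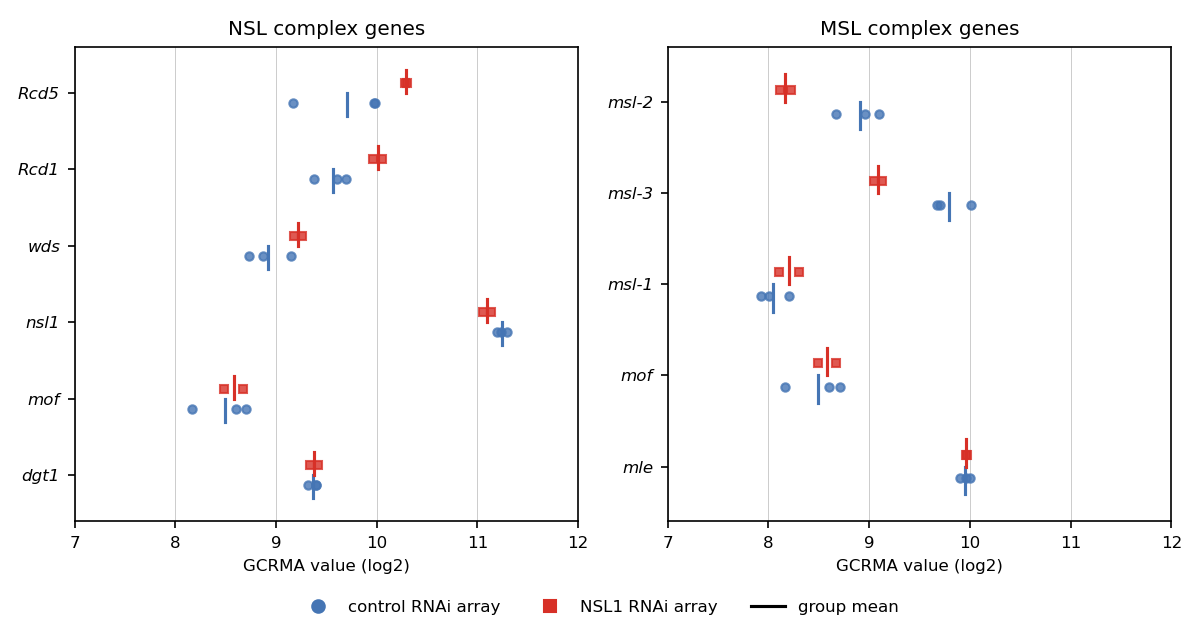
GCRMA log2 level (x axis) of the tested genes of the NSL complex (left) and the MSL complex (right) on each of the 3 control arrays (circles) and 2 NSL1-labelled arrays (squares), with group means as vertical bars. The nsl1 group means were 11.24 and 11.10, and msl-2 and msl-3 lay lower on both NSL1-labelled arrays than on every control array.

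Most of the transcriptome differed between the groups. Of 5946 genes, 2462 fell and 1414 rose (limma), so that 63.5% of the changed genes fell. With an absolute log2 difference of at least 1, 1523 genes fell and 762 rose. At the level of probe sets, 4607 of 7225 passed, 2776 lower and 1831 higher. The groups did not overlap for 81.1% of probe sets, against 20% by chance. Under cyclic loess, which assumes that most genes do not change, 52.4% of changed genes fell. After scaling to the poly-A control probe sets, which takes the same amount from bright and dim genes of an array, 92.2% fell. Without NSL1-labelled replicate 1, 890 genes rose (genes fallen and risen).

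The 12 largest rises included genes of cytochrome P450, glutathione S-transferase and glucuronosyltransferase families and others of varied function. Cyp9b1 and Cyp6d2, both cytochrome P450 genes, were at least 82.0-fold and at least 94.7-fold higher. IM33, an immune-induced peptide gene, was at least 67.5-fold higher, and LysX, a lysozyme gene, at least 26.8-fold higher. The transcript of osk, which organises the germ plasm of the egg, was at least 36.2-fold higher, at 2.22 ± 0.01 (SD, n = 3) on control arrays and 9.18 ± 0.12 (SD, n = 2) on NSL1-labelled arrays. GstD5, a glutathione S-transferase gene measured in both groups, rose by 6.71 (SE 0.25, limma adjusted p = 6.66e-05), and GstD6 was at least 21.7-fold higher. The glucuronosyltransferase genes Ugt302K1 and Ugt37E1 were at least 50.6-fold and at least 22.9-fold higher. The rest of the 12 were Obp49a, an odorant-binding protein gene (at least 65.2-fold), osy (at least 22.8-fold) and Cpr49Ac, a cuticle protein gene. Cpr49Ac rose by 6.30, with control arrays at 4.02, 3.41 and 3.46. Limma adjusted p-values of these 12 genes were at most 7.46e-05, and 7 genes with a bare CG or CR number ranked among them.

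The 12 largest falls by log2 difference were in genes of varied function, and their order is not one of depth, since most ended under a level of 4. GstE13, another glutathione S-transferase gene, fell (-5.44, SE 0.13, limma adjusted p = 2.99e-05), from 9.82 ± 0.08 (SD, n = 3) to 4.38 ± 0.23 (SD, n = 2). Lerp, which encodes a lysosomal enzyme receptor, fell (-5.10), with NSL1-labelled arrays at 4.62 and 3.15. Levels were at least 14.1-fold lower for Sdhaf3, an assembly factor of succinate dehydrogenase, and at least 16.9-fold lower for Urm1, which takes part in tRNA thiolation. Polr3G, of RNA polymerase III, was at least 20.7-fold lower and Nse1, of the Smc5/6 complex, at least 12.3-fold lower. The others were Ir76a (at least 22.2-fold lower), Gnpnat (about 20-fold or more), sgll (at least 15.7-fold), Targ3 (at least 11.4-fold), GstZ1 (at least 10.7-fold) and Mesh1 (at least 7.56-fold). Some of these bounds lie below falls measured down to a level above 4, such as that of mael (20.6-fold lower). Limma adjusted p-values of these 12 were at most 7.52e-04, and 13 genes with a bare CG or CR number ranked among them.

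**Figure D2:**
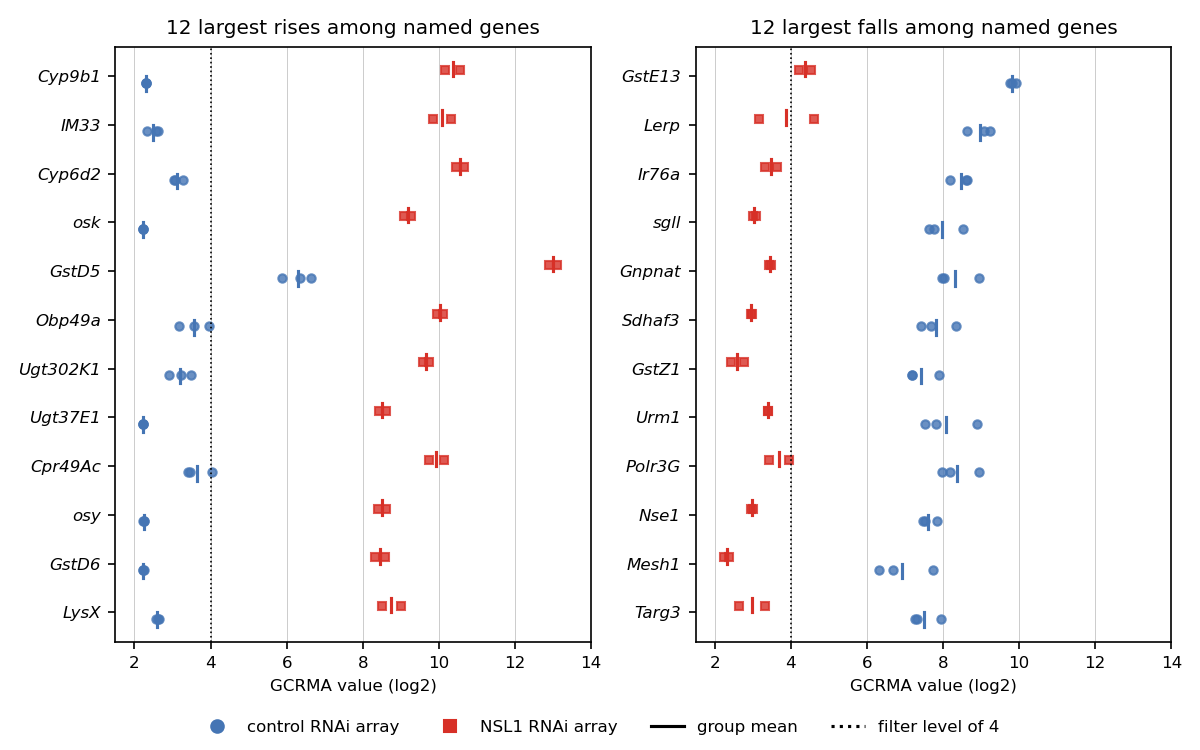
GCRMA log2 level (x axis) of the 12 largest rises (left) and 12 largest falls (right) among named genes, for each control array (circles) and NSL1-labelled array (squares), with group means as vertical bars and the filter level of 4 as a dotted line. Most rises start from controls under 4, as for osk at 2.22, and most falls end under 4, so that their folds are bounds.

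Genes for building mitochondria were lower. Of 71 mitochondrial ribosomal protein genes, 64 fell and 1 rose, with a median of -1.99 (limma camera adjusted p = 1.1e-07, and adjusted p = 0.716 with an estimated correlation). Adjusted over the list alone, 65 fell and 1 rose. Large falls were those of mRpL2 (-4.08), mRpL36 (-3.53) and mRpS17 (-3.51), and mRpS18C was at least 8.62-fold lower. In oxidative phosphorylation, 33 of 51 genes fell and 2 rose (34 and 2 adjusted over the list alone), with a median of -0.59 (limma camera adjusted p = 0.0134, and adjusted p = 0.797 with an estimated correlation). The complex I genes ND-13B (-2.37) and NdufA3 (-1.81) fell, while ATPsynepsilonL rose by 2.34 and UQCR-11 by 2.26. On control replicate 3, the median of the mitochondrial ribosomal genes lay 0.49 above that of the other controls, and that of oxidative phosphorylation 0.43 above. By fry, the respiratory genes did not pass (list: oxidative phosphorylation, limma adjusted p = 0.0615).

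Cell division and replication genes were lower as well. Among 36 DNA replication genes, 26 fell and 4 rose (27 and 4 adjusted over the list alone), with a median of -1.52 (limma camera adjusted p = 0.0321, and adjusted p = 0.811 with an estimated correlation). Psf2 of the GINS complex (-3.92) and DNAlig1, a DNA ligase gene (-3.29), fell. Psf1 was at least 11.2-fold lower and Orc4, of the origin recognition complex, at least 8.74-fold lower. Without NSL1-labelled replicate 1 the DNA replication call was lost (limma camera adjusted p = 0.0802), and with the filter at 6 it was lost as well (list: DNA replication, 0.076). Control replicate 3 lay above the other controls, by 0.62 for DNA replication and 0.48 for mitosis, and without it the medians were -1.25 and -0.75. For mitosis, 24 of 36 genes fell and 2 rose (26 and 3 adjusted over the list alone), with a median of -0.92 (limma camera adjusted p = 0.0213, and adjusted p = 0.797 with an estimated correlation). The kinase gene Mps1 was at least 6.93-fold lower, ida at least 2.25-fold lower, and cid, the centromeric histone gene (-2.51), and shtd, an anaphase-promoting complex gene (-2.03), fell. Centrosome and augmin genes fell in 23 of 29 cases and rose in 3, the same counts as adjusted over the list alone, with a median of -1.22 (limma camera adjusted p = 0.0247, and adjusted p = 0.716 with an estimated correlation). Cep97 was at least 7.5-fold lower and Sas-6, needed for centriole assembly, at least 6.92-fold lower, msd5 of augmin fell (-2.23), and Rcd6 rose by 2.62. Rcd6 lost its call without NSL1-labelled replicate 2 (limma adjusted p = 0.0506). The centrosomal call was lost (list: centrosome and augmin) under cyclic loess (median -0.53, limma camera adjusted p = 0.0596), after quantile normalization (-0.68, 0.0704) and with the filter at 6 (-0.86, 0.094).

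Transcription machinery genes were lower for RNA polymerase II. Of 35 RNA polymerase II and general transcription factor genes, 23 fell and 3 rose, also when adjusted over the list alone, with a median of -0.73 (limma camera adjusted p = 0.0311, and adjusted p = 0.711 with an estimated correlation). The largest falls were Xpd (-2.98), TfIIEbeta (-2.70), Tfb4 (-2.53) and CycH (-2.32). The other members of TFIIH and TFIIE (named after their values were seen) moved both ways, as mrn (-2.31), Cdk7 (-1.80) and Ssl1 (-0.45) fell, hay rose by 1.56 (limma adjusted p = 0.000256), and TfIIEalpha (0.01) and Tfb1 (-0.04) did not pass. Of 26 Mediator genes, 16 fell and 2 rose (the same adjusted over the list alone), with a median of -0.59, which did not pass (limma camera adjusted p = 0.062). Mediator passed without a filter (list: Mediator complex, limma camera adjusted p = 0.000655), at a minimum of 3 (0.0394) and by fry (0.00197). Here and below, passing without a filter or by fry does not set a list apart from other expressed genes. MED11 (-2.83), CycC (-2.81), MED20 (-2.44) and MED27 (-2.35) fell. Among 33 genes of chromatin, insulator and promoter-binding factors, 18 fell and 5 rose (19 and 5 adjusted over the list alone; limma camera adjusted p = 0.26, but 0.00562 without a filter, list: chromatin, insulator and promoter-binding factors, and 0.0208 by fry). The insulator protein genes su(Hw) (-1.75), BEAF-32 (-1.61) and Ibf2 (-1.54) fell, and Trf2, a TBP-related factor gene, rose by 1.90. Other histone acetyltransferase genes fell in 12 of 21 cases and rose in 3, as they did adjusted over the list alone (limma camera adjusted p = 0.301, but 0.0483 without a filter, list: other histone acetyltransferases, and 0.00586 by fry). Spt3 (-2.11) and chm (-1.30) fell, and Ada2b and Elp3 rose by 1.82 and 1.30. Elp3 lost its call without NSL1-labelled replicate 1 or 2 (limma adjusted p up to 0.0894).

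Genes for the cytosolic ribosome were among the brightest, with control means from 13.73 to 15.64 against a highest value of 15.8 on any array. Of 30 cytosolic ribosomal protein genes, 2 fell over all genes tested and 0 adjusted over the list alone, and the median was -0.05 (limma camera adjusted p = 0.975). Those were Rack1 (-0.40) and RpLP0 (-0.26). Of 15 other genes as bright as these, 6 fell and 0 rose (limma), with a highest difference of 0.18, so a rise of the ribosomal genes cannot be excluded. For the proteasome, 1 of 27 genes fell and 3 rose (1 and 0 adjusted over the list alone), with a median of 0.17 (limma camera adjusted p = 0.106). Rpt3R fell (-3.30), and Rpn1, Rpn2 and Prosalpha2 rose by 0.87, 0.52 and 0.47. Ribosome biogenesis had 2 fallen and 6 risen of 22 (1 and 1 adjusted over the list alone), with a median of 0.23 (limma camera adjusted p = 0.106). Bka (-2.68) and vito (-1.46) fell, and Nop17l and Fib, the fibrillarin gene, rose by 0.88 and 0.86. Without control replicate 3, 18 proteasome and 14 ribosome biogenesis genes rose, and 8 cytosolic ribosomal genes fell (limma), and the proteasome (limma camera adjusted p = 0.00146) and ribosome biogenesis (0.0136) passed. That array's median lay 0.55 above the other controls for the proteasome and 0.45 above them for ribosome biogenesis. Calls lost without NSL1-labelled replicate 1 or 2 were those of RpLP0, Rpn1, Rpn2, Prosalpha2, vito, Nop17l and Fib, with limma adjusted p up to 0.124, 0.117, 0.112, 0.181, 0.0996, 0.15 and 0.062. RpLP0, Rpn2 and Prosalpha2 also lost theirs without control replicate 1 or 2, Rpn1 without control replicate 2 and Nop17l without control replicate 1. Rack1 lost its call without control replicate 2 or NSL1-labelled replicate 1 (limma adjusted p up to 0.0736). Of 27 aminoacyl-tRNA synthetase genes, 11 fell and 8 rose, as they did adjusted over the list alone, with a median of -0.08, a mean of -0.62 and a test direction of up (limma camera adjusted p = 0.792). By fry the direction was down (limma adjusted p = 0.00589). TyrRS-m was at least 14.5-fold lower and GluRS-m at least 3.48-fold lower, and AsnRS-m (-3.60) and TrpRS-m (-3.56) fell.

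Genes of glutathione and xenobiotic metabolism were higher. Of 56, 33 rose and 10 fell (35 and 10 adjusted over the list alone), with a median of 1.50 (limma camera adjusted p = 2.01e-06, and adjusted p = 0.266 with an estimated correlation). Cyp9b1, Cyp6d2, GstD5 and GstD6 led this list. Of 100 measured genes of glutathione and xenobiotic metabolism, 44 lay under the filter, and without a filter the median was 0.26 (list: glutathione and xenobiotic metabolism, limma camera adjusted p = 1.44e-05). The control RNA was directed against a glutathione S-transferase, and no control array without it was given. Split after the values were seen, 13 of 26 transferase genes rose and 7 fell, with a median of 1.00, and 20 of the 30 other genes rose and 3 fell, with a median of 1.74.

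Stress and damage genes were higher in several lists. Of 10 apoptosis and p53 target genes, 8 rose and 1 fell, also when adjusted over the list alone, with a median of 1.03 (limma camera adjusted p = 0.0134, and adjusted p = 0.695 with an estimated correlation). The DNA repair genes Ku80 and mre11 rose by 2.99 and 1.11, p53 itself by 1.59, and RnrL, a ribonucleotide reductase gene that the replication list also holds, by 1.09. Of 14 measured genes of this list 4 lay under the filter, and without a filter the median was 0.52 (list: apoptosis and p53 targets, limma camera adjusted p = 0.00294). Amino acid and unfolded protein stress genes rose in 9 of 20 cases and fell in 3, as they did adjusted over the list alone, with a median of 0.26 (limma camera adjusted p = 0.0247, and adjusted p = 0.711 with an estimated correlation). Gadd45, trbl and Ero1L, an oxidase of the endoplasmic reticulum, rose by 3.52, 2.23 and 1.40, and CG11899 fell (-1.89). Glycolysis and TCA cycle genes rose in 7 of 15 cases and fell in 1 (6 and 1 adjusted over the list alone), with a median of 0.48 (limma camera adjusted p = 0.0134, and adjusted p = 0.711 with an estimated correlation). The glycolytic genes Pglym78, Tpi and Hex-A rose by 1.03, 1.00 and 0.87, and mAcon1, the aconitase gene, fell (-0.70). Under cyclic loess the call was lost for amino acid and unfolded protein stress (median 0.45, limma camera adjusted p = 0.0596) and for glycolysis and TCA cycle (0.062), as it was after quantile normalization (list: amino acid and unfolded protein stress, 0.0625, and list: glycolysis and TCA cycle, 0.0704). Of 10 heat shock protein genes, 2 rose and 0 fell (1 and 0 adjusted over the list alone; limma camera adjusted p = 0.0696). These were Hsc70-3 (0.54) and Hsp60A (0.42). The heat shock proteins passed without control replicate 1 (limma camera adjusted p = 0.0407) and without control replicate 2 (0.0396), and without a filter (list: heat shock proteins, 0.0492). Control replicate 3 lay 0.68 below the other controls for heat shock proteins, and without it their median was 0.19 instead of 0.48 (limma camera adjusted p = 0.237). Without NSL1-labelled replicate 1 or 2, RnrL, Tpi, Hsc70-3 and Hsp60A lost their calls (limma adjusted p up to 0.0662, 0.059, 0.0647 and 0.113), Hsp60A also without control replicate 1 or 2, and mAcon1 lost its call without NSL1-labelled replicate 2 (0.0608).

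Immune and signalling genes moved both ways. Of 11 innate immune genes, 6 rose and 1 fell, also when adjusted over the list alone, with a median of 0.50 (limma camera adjusted p = 0.0318, and adjusted p = 0.711 with an estimated correlation). Besides LysX, the antimicrobial peptide genes Drs and CecB rose by 4.25 and 0.87, and PGRP-LF by 1.01. Of 21 measured immune genes, 10 lay under the filter, and the median was 0.27 without a filter (list: innate immune effectors and regulators, limma camera adjusted p = 0.00498) and 0.79 under cyclic loess. With the filter at 6 the call was lost (limma camera adjusted p = 0.076). JAK-STAT and JNK targets had 4 fallen and 3 risen genes of 14, the same adjusted over the list alone, with a median of 0.06, a mean of -0.01 and a test direction of up (limma camera adjusted p = 0.588). The JAK-STAT receptor gene et (-1.39) and the TNF gene egr (-0.92) fell, and puc, a JNK phosphatase gene, and PGRP-LA rose by 1.01 and 0.92. Ecdysone response genes rose in 2 of 11 cases and fell in 1, also when adjusted over the list alone (limma camera adjusted p = 0.227, and 0.0405 by fry), with Eip93F and Eip63E up by 3.34 and 0.76 and br down (-0.62). With the mean of its probe sets br was -0.06 and did not pass (limma adjusted p = 0.603). RNA interference and microRNA machinery had 4 fallen and 2 risen genes of 15 (4 and 0 adjusted over the list alone; limma camera adjusted p = 0.975, and 0.0405 by fry). Trax (-3.48), drosha (-2.81) and trsn (-1.10) fell, and Hen1 was about 8-fold or more lower. PGRP-LF, CecB and br lost their calls without NSL1-labelled replicate 1 or 2 (limma adjusted p up to 0.0623, 0.156 and 0.06), and puc without replicate 1 (0.0575).

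No list of cell type markers passed camera at the filter of 4. S2 cells resemble plasmatocytes, the fly's phagocytes, and 11 of 21 plasmatocyte markers fell and 2 rose, as they did adjusted over the list alone (limma camera adjusted p = 0.536). The receptor gene NimC1 rose by 2.92, and the matrix genes LanB2 (-1.46), LanB1 (-1.05) and Pxn (-1.01) fell, but with the mean of its probe sets Pxn was 0.16 and did not pass (limma adjusted p = 0.565). Of 9 crystal cell and lamellocyte markers, 4 rose and 1 fell, also when adjusted over the list alone (limma camera adjusted p = 0.106). These markers passed without a filter (list: crystal cell and lamellocyte markers, limma camera adjusted p = 0.0233), at a minimum of 3 (0.0324) and by fry (0.00218). The lamellocyte genes atilla and ItgaPS4 were at least 9.77-fold and at least 5.64-fold higher, betaTub60D rose by 2.91, and PPO2, a prophenoloxidase gene, fell (-1.73). Of 5 neuron markers, 3 rose (1 adjusted over the list alone; limma camera adjusted p = 0.193, and 0.0259 by fry), namely brp by 1.37, elav by 0.48 and cac by 0.36. Germline genes fell in 7 of 12 cases and rose in 3, as they did adjusted over the list alone (limma camera adjusted p = 0.517). Here mael fell (-4.37), zpg was at least 10.6-fold lower, and osk and qin were higher, qin at least 3.91-fold. Too few genes passed the filter to test muscle markers (2 of 4 rose, sls at least 7.12-fold and bt by 2.15) or fat body and gut markers (1 of 1 rose, apolpp by 1.43), with the same counts adjusted over the list alone. Under the filter lay 12 of 16 measured muscle markers, 14 of 15 fat body and gut markers, 12 of 17 neuron markers and 18 of 30 germline genes. Without NSL1-labelled replicate 1 or 2, betaTub60D, PPO2, elav, cac and apolpp lost their calls (limma adjusted p up to 0.106, 0.118, 0.204, 0.154 and 0.136), elav and cac also without control replicate 1 or 2.

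**Figure D3:**
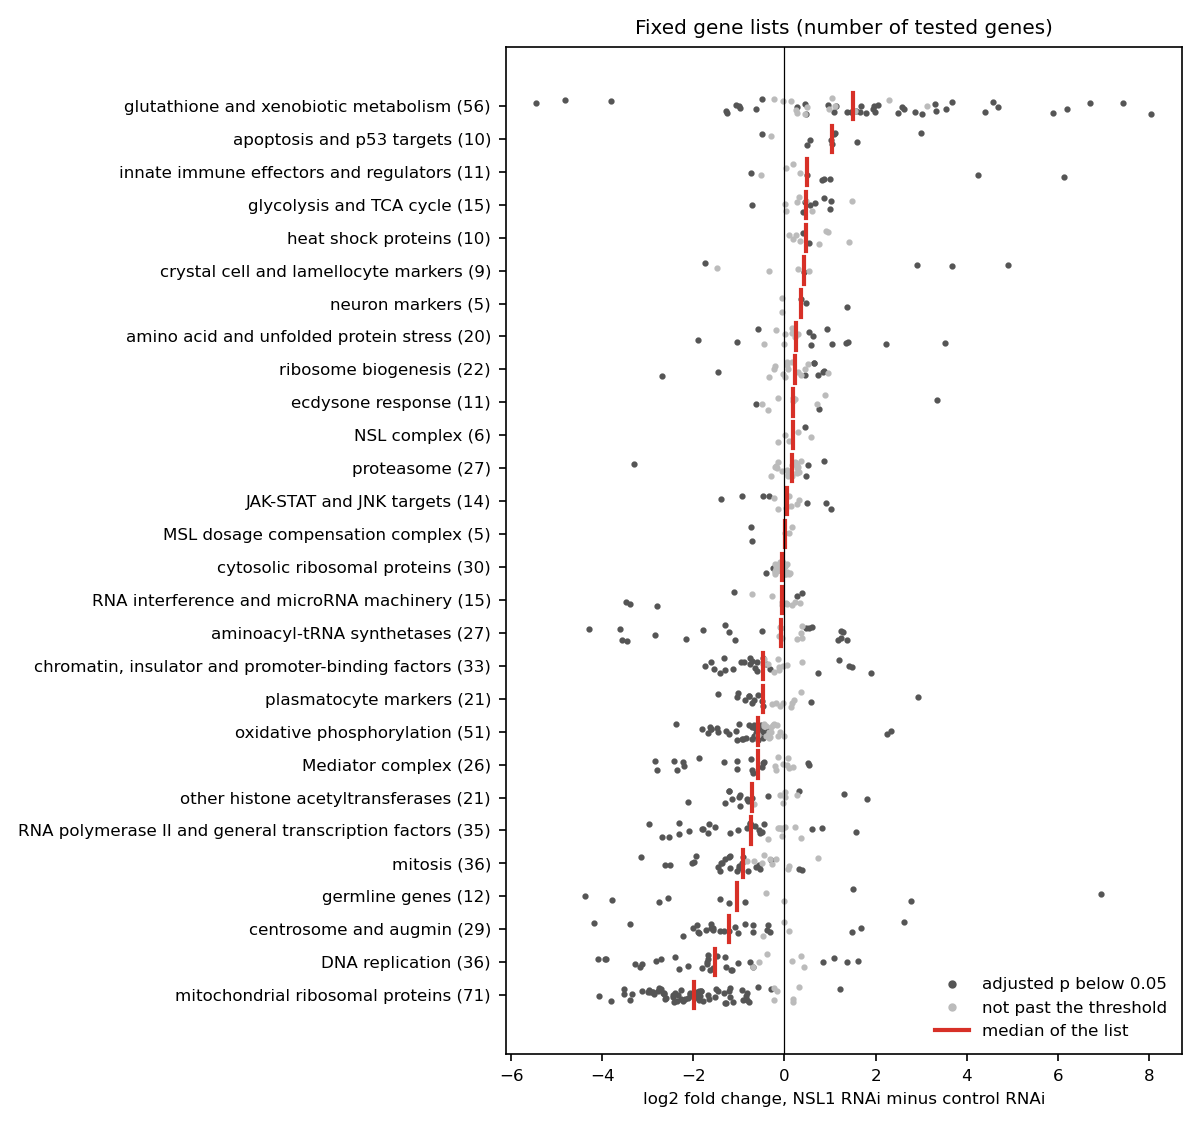
Log2 difference, NSL1-labelled minus control (x axis), of every tested gene of the 28 tested lists (rows, with the number of genes), dark where the limma adjusted p was below 0.05 and light otherwise, with list medians as red bars. Mitochondrial ribosomal genes lie lowest, with a median of -1.99, and glutathione and xenobiotic metabolism highest, with a median of 1.50.

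MOF also acts in dosage compensation of the male X chromosome, so X-linked and autosomal genes were compared. The median difference was -0.10 for 1000 X-linked genes and -0.20 for 4931 autosomal genes. X minus autosomes was 0.11, between 0.07 and 0.15 over the 6 pairs of single arrays, and the lists did not stand apart (limma camera p = 0.402, and p = 0.709 with an estimated correlation). Among X-linked genes 36.3% fell and 23.5% rose, and among autosomal genes 42.4% fell and 23.8% rose.

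Among genes past the filter of 4, the median difference was lower in weakly expressed genes. From the lowest to the highest quartile of mean expression, the median log2 difference was -0.83, -0.43, -0.06 and -0.00, and 54.3%, 50.3%, 36.5% and 24.5% of genes fell. Over the 6 pairs of single arrays, the lowest quartile lay between -0.86 and -0.74 and the highest between -0.02 and 0.01. The filter and the quartiles used the mean over 3 control and 2 NSL1-labelled arrays. A gene seen only on control arrays therefore passed at a lower level than one seen only on NSL1-labelled arrays. This can add falls to the lowest quartile, and how much of the trend it accounts for was not tested. The order of the quartiles depended on the filter and the normalization. Fold change by expression level: quartile 1 and quartile 2 were -0.28 and -0.48 at a minimum of 3, and without a filter both were 0 and quartile 3 was -0.56. The lowest quartile was -0.22 after quantile normalization and -0.16 under cyclic loess. Hybridization control probe sets under a level of 9 read higher on both NSL1-labelled arrays, by 0.68 and 0.76.

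Array agreement differed within the controls. The SD of log2 differences was 0.180 between control replicates 1 and 2, 0.545 and 0.463 between control replicate 3 and these, and 0.244 between the NSL1-labelled arrays. Between groups it ran from 1.49 to 1.73. Over tested probe sets, control replicate 3 minus 1 correlated at -0.30 with the NSL1-labelled mean minus control replicate 2. With control replicates 1 and 2 exchanged, the correlation was -0.24. Control replicate 3 thus differed from the other controls partly along the contrast, away from the NSL1-labelled arrays. Against their mean, its median was 0.18 over genes called fallen and -0.09 over genes called risen, calls that used this array. Without control replicate 3, 5255 probe sets passed (probe sets changed, limma).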

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

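The tests in this part were chosen after the control probe sets had been looked at, except the count of other splits of the arrays.

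Control probe sets that no comparison used read higher on the NSL1-labelled arrays. The shift was 0.42 for 18 hybridization control probe sets, 1.12 for 20 poly-A control probe sets and 0.45 for 3 probe sets of 18S ribosomal RNA. These are signals outside the main measurement, above the level on the control arrays.

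Poly-A controls are bacterial transcripts that the standard protocol adds to total RNA before labelling, so their shift may reflect less messenger RNA per amount of total RNA in the NSL1-labelled samples. The mean 18S shift exceeded that of the brightest hybridization controls by 0.335, which goes with this explanation, but the 3 probe sets differed (0.648, 0.521 and 0.167). On NSL1-labelled replicate 2 the lowest of them shifted by 0.110, inside the range of the brightest hybridization controls (0.107 to 0.173). A shift with signal level left by the normalization stays open, because the excess of the poly-A shift over hybridization controls of the same level was 0.365 on average but 0.653 on one array and 0.0772 on the other. More control RNA added per sample cannot be told apart from it either, since the 4 poly-A transcripts shifted alike, within 0.273. If the poly-A controls were taken as the reference, 4386 genes fell and 369 rose (genes fallen and risen), so the balance of falls and rises depends on this point. That scaling takes the same amount from every gene of an array. The poly-A controls had a control mean of 6.35, and hybridization controls shifted by 0.720 under a level of 9 but by 0.110 above 13. The poly-A shift need not hold for bright genes, so these counts may overstate the falls.

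Of the 10 splits of the 5 arrays into 3 and 2, 1 split, the real one, called 4607 probe sets, and the highest of the other splits called 0 (limma). With 10 splits no share under 0.05 can be reached. Every other split puts arrays of both labels into a group, so the difference between labels enters its residual spread. The 0 calls of those splits therefore do not measure chance.

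The lower quartiles of expression fell more. Hybridization controls under a level of 9 read higher by 0.720 on the NSL1-labelled arrays. These controls are not transcripts of the cells, so their shift does not show whether dim genes were read too low. A technical source of the trend therefore stays open. Under cyclic loess the lowest quartile minus the highest was -0.15, against -0.82 as deposited.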

How the results depend on the processing

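Scaling to the poly-A controls and raising values below 4 to 4 were chosen after seeing the data. All other alternatives were set before.

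The number of probe sets changed ran from 3220 to 5255 when each array was left out, and 2696 passed with an absolute log2 difference of at least 1. Genes fallen ran from 1863 to 2710 and genes risen from 890, without NSL1-labelled replicate 1, to 1696. The NSL1 transcript ran from -0.18 to -0.10 and was -0.28 after quantile normalization (limma adjusted p = 0.0463). Over all 16 alternatives run for it, the difference lay between -0.28 and -0.02 (limma adjusted p up to 0.88). Where a group keeps 1 array, that array is assumed to vary like the others. Lists lower ran from 5 to 6 and lists higher from 5 to 7. With the filter at 6, 3 list calls were lost, and 5 were gained without a filter and 2 at a minimum of 3. Lists higher numbered 3 under quantile normalization and 3 under cyclic loess. With the correlation estimated per list, 0 lists were lower and 0 higher, and with fry 10 were lower and 8 higher. Fry, which does not compare a list with other genes, turned aminoacyl-tRNA synthetases from up to down (median -0.0793, limma adjusted p = 0.00589). Why the direction turned was not tested. With the mean of a gene's probe sets, Pxn went from -1.01 to 0.16 (limma adjusted p = 0.565), and the cause was not tested.

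Genes fallen and risen, percent of changed genes that fell, was 52.4% under cyclic loess and 92.2% (4386 fallen, 369 risen) under poly-A scaling. The latter takes the same amount from bright and dim genes, although the shift of the hybridization controls differed with level. The median shift per gene was 0.13 under median centring, 0.13 under quantile normalization, 0.22 under cyclic loess and -1.12 under poly-A scaling, and the median of all genes, -0.18 as deposited, was -0.05, -0.11, -0.02 and -1.30. Of the 3876 genes called, 3444 kept the call and direction under cyclic loess and 2827 under poly-A scaling.

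The quartile medians moved as follows. For fold change by expression level: quartile 1, the median was 0 without a filter, since most added probe sets lie at the floor, -0.28 at a minimum of 3, -0.75 at a minimum of 6, -0.70 with median centring, -0.22 after quantile normalization, -0.16 under cyclic loess and -0.77 with values raised to 4. For fold change by expression level: quartile 2, it was 0, -0.48, -0.32, -0.31, -0.13 and -0.00873 in the first 6 of these. For fold change by expression level: quartile 3, it was -0.56 without a filter, -0.0142 at a minimum of 6, 0.0616 with median centring, -0.0829 after quantile normalization and 0.00703 under cyclic loess. For fold change by expression level: quartile 4, it was -0.0272 without a filter, 0.12 with median centring and -0.0862 after quantile normalization, and leaving out arrays gave -0.0149 to 0.00336.

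The replicate number as a block gave 5271 probe sets changed and quartile 4 at -0.0149. The samples share only a number, as same-numbered deviations correlated at 0.259 and -0.0774 over 2 pairs, and the block in effect drops control replicate 3. X chromosome against autosomes passed under none of the 18 alternatives run (limma camera p from 0.178 to 0.773). Signal over background limits genes near the floor, whose folds are bounds. Of 129 named genes, 30 lost the call without a filter, 25 without each NSL1-labelled array and 13 by least squares without moderation.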

Other observations

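The tests of aminoacyl-tRNA synthetases, of symbol families and of the glutathione S-transferases were chosen after the results were seen. Those of neighbouring genes that fell together were chosen before.

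Aminoacyl-tRNA synthetases split by compartment. Of 12 genes named as mitochondrial, 10 fell and 1 rose, with a median of -1.98, and of 15 others 1 fell and 7 rose, with a median of 0.39. The difference of medians was -2.37 (two-sided permutation test over genes, p = 0.00029), and genes are not independent replicates. Among the mitochondrial genes, LeuRS-m rose by 0.62 and AspRS-m did not pass (-0.11, limma adjusted p = 0.465). Among the others, TyrRS fell by 0.50 (all named after their values were seen).

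Families of genes that share a symbol stem were scanned, 35 with at least 8 genes. Ugt genes rose in 11 of 13 cases, with a median of 2.69 (limma camera adjusted p = 2.95e-05), Cyp genes in 16 of 29 (median 1.57) and GstD genes in 8 of 9 (median 3.54). EMC genes, of the membrane protein insertion complex, fell in 8 of 9 cases, with a median of -0.89 (limma camera adjusted p = 0.0318). The stems ND, mRpL and mRpS also passed, with 9 of 10, 39 of 44 and 23 of 25 genes fallen. With an estimated correlation 0 families passed in limma's camera, and the adjusted p was 0.349 for Ugt and 0.895 for EMC.

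The rise in glutathione and xenobiotic metabolism may have a technical source, since the control RNA was directed against a glutathione S-transferase and could have lowered related transcripts in the control cells. The 30 genes of the list that are not transferases had a median 1.92 above that of all genes (limma camera p = 8.1e-08, and p = 0.0503 with an estimated correlation). A loss of matching transferase transcripts alone would not reach these genes, but an indirect effect of the control RNA on them stays open. Some of them, such as Cyp9b1 with a control mean of 2.31, passed the filter only through the NSL1-labelled arrays. For the 26 transferase genes, 1.18 above all genes, a technical source stays open as well, since every control array had this RNA. An effect of NSL1 depletion on detoxification genes is the biological alternative. It cannot be told apart from an effect of the control RNA, since no control array without that RNA was given. The nsl1 probe set did not show a depletion either.

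Genes that fell lay next to each other more often than their levels predict. Both genes fell in 773 of 3525 neighbouring pairs, against a mean of 608.8 in 10000 shuffles among genes of the same level (one-sided permutation p = 1e-04, the smallest they can give). Leaving out pairs that share a symbol stem kept 3473 pairs and 98.6% of the excess. Too few pairs were removed for this to decide about duplicated genes, and pairs with bare CG or CR numbers were never counted as sharing a stem. Pairs with 1 gene between them kept 92.9% of the relative excess, so gene-dense regions may hold more genes that fell, while gene orientation and shared promoters were not tested and stay open. Without pairs that share a symbol stem, both fell in 726 of 3109 pairs within 1 kb (544.0 in shuffles) and in 37 of 364 pairs farther apart (57.0). Both rose in 218 of all pairs (197.5 in shuffles, one-sided permutation p = 0.0519), and in 199 without pairs that share a symbol stem (194.6, p = 0.37). By distance, both rose in 157 of the close pairs (173.8 in shuffles) and in 42 of the farther pairs (20.8, one-sided permutation p = 1e-04, the smallest they can give). No prediction was set for rises or for the split by distance.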
